A study of Homo sapiens with 9 samples.

How the data were processed

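Gene expression was measured by RNA sequencing of total RNA from KG-1a cells, a human acute myeloid leukaemia line that expresses CD34. The 9 libraries formed 3 groups of 3, taken from the sample labels: wild-type cells (WT), PRMT2 knockout clone 1 and PRMT2 knockout clone 2, both made with CRISPR/Cas9. Per the labels, the clones and the control cells were expanded under the same culture conditions and received no drug. The labels do not say whether the replicates of a group were separate cultures. If they were not, the p-values measure only the spread between these samples. Even if they were, the p-values of the main fit cover the spread within each group and not the spread between clones. The labels also do not say whether the WT cells were cloned from a single cell.

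For each library the authors deposited raw counts of read pairs per gene, made with STAR in 2-pass mode on the genome build GRCh38. The versions of STAR and of its gene annotation are not stated. Each file of counts holds 3 countings per gene, one without regard to strand and one for each strand, and 4 totals for pairs not assigned to a gene. The authors also deposited 1 table that compares both clones together with WT, with raw counts, log2 fold changes (log2) and p-values with their adjusted values (p_value), made with DESeq2. The raw counts in that table were equal to the counting without regard to strand in all 9 libraries.

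The counting to use was fixed by a rule. The counting without regard to strand would have been used if each strand held between 35% and 65% of the stranded counts. One strand held 92.03% to 92.31% in the 9 libraries, so its counting was used. All 60605 gene identifiers were read, and 60463 were found in the annotation (GENCODE release 44), which gave positions and gene types. Symbols of the named genes came from the authors' deposited table, and 40591 identifiers had a symbol.

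Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 20655 genes, and libraries were scaled by the trimmed mean of M-values. A quasi-likelihood negative binomial model with robust estimation was fitted to all 9 libraries with 1 coefficient per group, and each contrast was tested with its F test. The contrasts were clone 1 against WT, clone 2 against WT, the mean of both clones against WT, and clone 2 against clone 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 together with an absolute log2 fold change of at least 1, the thresholds that the series text states. The adjusted p-values below come from this edgeR fit unless another tool is named. Standard errors (SE) were derived as the absolute log2 fold change divided by the square root of F. They are approximate, above all for large changes, and do not measure the error of a fold change where a group has few counts. Levels are CPM, the counts of a gene divided by the scaled library total and multiplied by 1e6, with the standard deviation over the 3 libraries of a group.

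Gene lists were tested with camera in limma 3.58.1 on log2 CPM with voom weights, with a preset correlation between genes of 0.01, and adjusted over the 43 lists. Camera with an estimated correlation and the directional p of fry were the alternatives. The 43 lists hold 1161 genes, of which 1160 were found and 943 passed the filter. The lists, the tests, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the PRMT family, and the 12 largest rises and 12 largest falls among genes called in both clones in the same direction. For the latter it asked that all 6 knockout libraries lie outside the range of the 3 WT libraries, for a mean of at least 5 CPM in the highest group, and for a symbol. It also named the 8 largest differences between the clones in each direction, among genes called in that contrast and in at least 1 clone. It further named up to 4 members, by smallest adjusted p, of each list that was called or had at least 3 called members, and the NF-kB targets, chemokines and cytokines called in both clones. Other genes are said to have been chosen after their values were seen. Not every gene that the rule named is reported here.

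Depth was between 28006342 and 43149410 counted read pairs per library, which were 25.93% to 29.59% of all pairs. A floor of 3 counts came to between 0.07 and 0.107 CPM per library. Where all libraries of a group had 0 counts, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% counting interval. Such bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Between replicates of a group, the chi-squared per degree of freedom of the counts was 2.53 to 5.15, except 49.55 and 50.51 for the pairs with KO clone 1 replicate 1, and the correlation of log2 CPM across genes was 0.991 to 0.994, where genes are not independent replicates.

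The pipeline was tested on simulated data. With 100 genes changed by 1.5 on the log2 scale and 100 changed by 3, it called 99 and 100 of them, and it called 2 of 20455 unchanged genes. In a simulated comparison with no change, it called 0 of 20655 genes with edgeR, and 1 passed the adjusted p alone.

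The alternatives were size factors by relative log expression, no filter on low counts, a filter of at least 1 CPM in 3 libraries, no fold minimum, counts without regard to strand, and only the groups compared. DESeq2 1.42.0 was run with and without shrinkage by apeglm 1.24.0. With apeglm, the mean of both clones was fitted as 2 groups, 6 against 3 libraries. Further alternatives were a 2-group fit of 6 against 3 libraries, a replicate block, and each library left out in turn. Some alternatives were added after the data had been seen: a DESeq2 fit in the layout of the authors' deposited table, the same fit with unadjusted p-values, and other thresholds for genes that were off in both clones. Gene Ontology enrichment, which the series text mentions, was not analysed here.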

Results

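The transcriptomes of KG-1a cells with intact PRMT2 and of 2 PRMT2 knockout clones were compared, with 3 libraries per group. KG-1a is a line of immature myeloid leukaemia cells. PRMT2 is a member of the protein arginine methyltransferase family. The design asks which genes change when PRMT2 is lost and which changes both clones share. Counted read pairs in WT replicates 1 to 3 were 38282761, 40554236 and 32542001. In clone 1 they were 28006342, 31757786 and 32125938, and in clone 2 they were 41463714, 37745011 and 43149410. Each library had a count for 27618 to 30049 of 60605 genes.

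The 9 libraries separated by group. The first principal component of log2 CPM held 54.4% of the variance and placed WT at a mean of -61.4, clone 1 at 38.6 and clone 2 at 22.8. The second held 18.2% and separated the clones, with clone 1 between 25.3 and 31.9, clone 2 between -35.1 and -32.0, and WT between 4.2 and 6.7. KO clone 1 replicate 1 stood apart in its composition. In that library 13.33% of read pairs mapped to several places, against 3.86% to 4.51% in the other 8. The mitochondrial rRNA genes MT-RNR1 and MT-RNR2 reached 13112.9 and 13524.3 CPM in it, against 14.8 to 51.9 and 15 to 40.7 CPM elsewhere. Mitochondrial mRNAs took 3.83% of its counts, against 3.12% to 3.57%. Without this library, the numbers of called genes were 1624 for clone 1, 1319 for clone 2, 1465 for their mean, 578 between the clones and 934 in both clones, all within 1.5 times the numbers given with it.

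**Figure D1:**
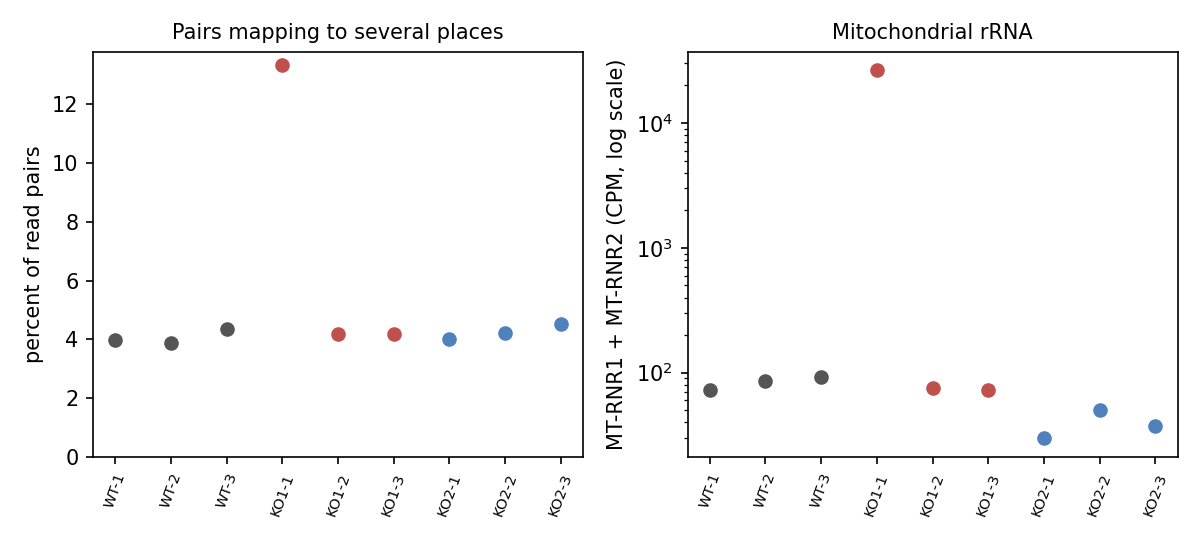
Left, percent of read pairs that mapped to several places, and right, the summed level of the mitochondrial rRNA genes MT-RNR1 and MT-RNR2 in CPM on a log scale, 1 point per library (KO1-1 is KO clone 1 replicate 1). KO clone 1 replicate 1 lies at 13.33% multimapping pairs, above the 3.86% to 4.51% of the other 8 libraries.

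PRMT2 RNA was lower in both clones than in WT and was still present at about the same level in each. PRMT2 (ENSG00000160310, GRCh38 chromosome 21, 46635595 to 46665124) was at 39.4 ± 0.393 CPM in WT, 20.7 ± 0.544 CPM in clone 1 and 21.2 ± 0.153 CPM in clone 2 (SD, n = 3 libraries each). All 6 knockout libraries were below the 3 WT libraries. The remaining level was 52.6% of WT in clone 1 and 53.9% in clone 2. The log2 fold change was -0.93 in clone 1 (SE 0.055, adjusted p = 7.79e-18) and -0.89 in clone 2 (SE 0.054, adjusted p = 1.51e-17). The mean of both clones was -0.91, so the decrease passed the adjusted p but fell short of the fold minimum. The clones differed by 0.04 (SE 0.057, adjusted p = 0.708). RNA levels do not show whether protein was made. The series text states that the clones were checked for DNA, RNA and protein but gives no target sites, so the edited exon was not examined.

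The other 7 measured family members changed far less than the fold minimum. PRMT1, the main asymmetric arginine methyltransferase, fell by 0.27 on the log2 scale in clone 1 (adjusted p = 1.49e-08) and was at -0.02 in clone 2 (adjusted p = 0.787). CARM1 fell by 0.22 in clone 1 (adjusted p = 5.7e-05) and was at 0.06 in clone 2 (adjusted p = 0.302). PRMT5, which makes symmetric dimethylarginine, rose by 0.22 in clone 2 (adjusted p = 8.89e-06), and PRMT6 rose by 0.21 there (adjusted p = 0.00043). PRMT3, PRMT7 and PRMT9 passed the adjusted p in neither clone. PRMT8 did not pass the filter on low counts. Among the genes next to PRMT2, chosen after their values were seen, S100B was at only 1.24 CPM in WT. It fell by 2.12 in clone 1 (adjusted p = 1.63e-06) and was at -0.63 in clone 2 (adjusted p = 0.0705). The neighbours LSS, MCM3AP, YBEY, C21orf58, PCNT and DIP2A changed little. In both clones they lay between -0.36 (YBEY, clone 2) and 0.19 (MCM3AP, clone 2).

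**Figure D2:**
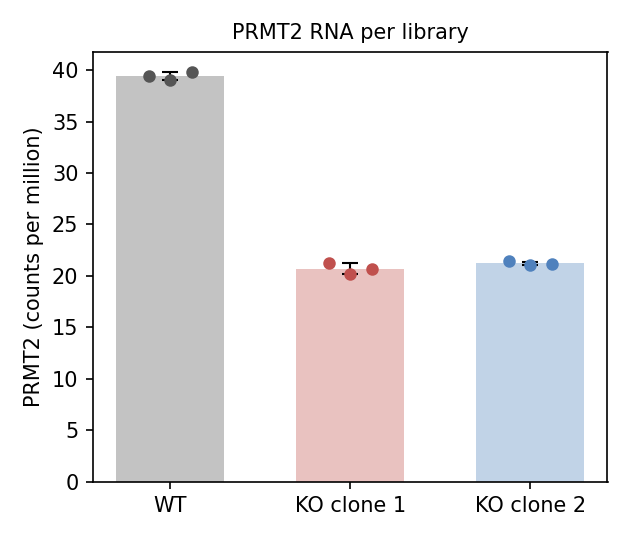
PRMT2 RNA in CPM in WT, KO clone 1 and KO clone 2, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3). The 6 knockout libraries lie near 21 CPM, all below the WT mean of 39.4 CPM.

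Both clones shared a large set of changes in which falls outnumbered rises past the fold minimum. The haematopoietic transcription factor TAL1 rose about 10-fold in both clones, the interferon-inducible IFITM3 rose, and the endothelial adhesion gene ESAM rose. In the mean of both clones, lists of T and NK cell markers, interferon-stimulated genes, MHC class I genes, cytokines and adhesion genes were lower, and of these the interferon and MHC class I lists held in each clone with an estimated correlation. By thresholds chosen after the data had been seen, 25 genes at 5 CPM or more in WT were below 0.3 CPM in both clones, and 14 were when counts disregarded strand. Of 20655 genes tested, 1349 were called in the mean of both clones against WT, 414 higher and 935 lower. At the adjusted p alone, 3386 were higher and 3896 lower. In the separate comparisons, 897 genes were called in both clones in the same direction, 269 higher and 628 lower. Protein-coding genes made up 161 of the shared rises and 441 of the shared falls, and long non-coding RNAs made up 63 and 124.

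Among the named rises, CYP7B1, TUSC3 and TAL1 had the largest mean log2 fold changes. TAL1 (ENSG00000162367, chromosome 1, 47216290 to 47232225), a master regulator of blood stem cells and erythroid cells, went from 7.13 ± 0.577 CPM in WT to 72.0 ± 4.2 in clone 1 and 67.3 ± 0.352 in clone 2. Its mean log2 fold change was 3.29 (SE 0.054, adjusted p = 1.59e-37). CYP7B1 (ENSG00000172817), an oxysterol hydroxylase, went from 0.213 ± 0.134 CPM to 6.54 ± 0.560 and 7.62 ± 0.477, a mean log2 fold change of 4.96 (SE 0.196, adjusted p = 5.76e-24). ATP8A2 (ENSG00000132932), a phospholipid flippase, went from 22.2 ± 0.591 CPM to 188 ± 2.66 and 120 ± 3.03, a change of 2.75 (SE 0.036, adjusted p = 4.17e-41). STON2 (ENSG00000140022), an endocytic adaptor, went from 4.90 ± 0.577 CPM to 34.3 ± 0.367 and 42.8 ± 1.70. TUSC3 went from 0.441 CPM to 7.93 in clone 1 and 2.85 in clone 2. The remaining named rises were PLEKHG1 at 3.26, HS3ST3B1 at 3.14, WFDC1 at 3.03, ANKRD55 at 2.85, SPTB at 2.76, PGAP4 at 2.70 and SMPDL3B at 2.60 in mean log2 fold change. SPTB, which encodes a spectrin of the red cell membrane, was at 0.24 and not called when counts disregarded strand. For all 12, each of the 6 knockout libraries was above each WT library, which the rule for naming them required.

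The largest shared falls were genes expressed in WT and almost silent in both clones. SNHG14 (ENSG00000224078, chromosome 15, 24978583 to 25420336), a long non-coding RNA of the imprinted Prader-Willi and Angelman region, went from 79.1 ± 1.68 CPM in WT to 0.096 ± 0.109 and 0.122 ± 0.0418. Its mean log2 fold change was -9.45 (SE 0.106, adjusted p = 1.63e-39), and -1.77 when counts disregarded strand. ATP10A (ENSG00000206190), a phospholipid flippase gene of the same chromosome, went from 32.6 ± 0.697 CPM to 0 counts in clone 1, at least 1000-fold lower, and 1 count in clone 2, a ratio of 3960 (95% counting interval 711 to 157000). H3C13 (ENSG00000183598), a histone H3 gene, was at 35.2 ± 2.12 CPM in WT and had 0 counts in clone 1, at least 1080-fold lower, and 3 counts in clone 2, a ratio of 1420 (485 to 6880). RBPMS2 was at 31.1 ± 1.44 CPM in WT, with 5 counts in clone 1 and 0 counts in clone 2, at least 1260-fold lower. Its call was lost with apeglm shrinkage in a 2-group fit, where its log2 fold change was -0.18. LITAF, which encodes a lysosomal and endosomal protein induced by lipopolysaccharide, went from 17.7 ± 1.04 CPM to 0.0347 ± 0.0367 in clone 1 and 0.0506 ± 0.0284 in clone 2.

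The zinc transporter SLC30A4 had 5.31 ± 0.605 CPM in WT and 0 counts in both clones, at least 163-fold lower in clone 1 and at least 215-fold lower in clone 2. The amino acid transporter SLC16A10 had 5.22 ± 0.339 CPM in WT and 0 counts in both, at least 160-fold and 211-fold lower. DNTT, the terminal transferase of immature lymphocytes, had 8.11 ± 0.156 CPM in WT and 0 counts in clone 1, at least 249-fold lower, and 0.150 ± 0.0714 CPM in clone 2. NEURL1 was at 12.1 CPM in WT, with 3 counts in clone 1, a ratio of 372 (127 to 1810), and 0 counts in clone 2, at least 490-fold lower. CNNM1 was at 9.10 CPM in WT, with 0 counts in clone 1, at least 279-fold lower, and 2 counts in clone 2, a ratio of 555 (153 to 4590). The transcription factor NFE2L3 was at 9.11 CPM in WT with 1 count in each clone, ratios of 840 (150 to 33200) and 1110 (198 to 43800). When counts disregarded strand, NFE2L3 was at a mean log2 fold change of -0.66 and not called, and SLC30A4 at -6.56, NEURL1 at -2.79 and CNNM1 at -4.51 were called with smaller falls. The pseudogene RBMY2QP on chromosome Y completed the 12 named falls.

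**Figure D3:**
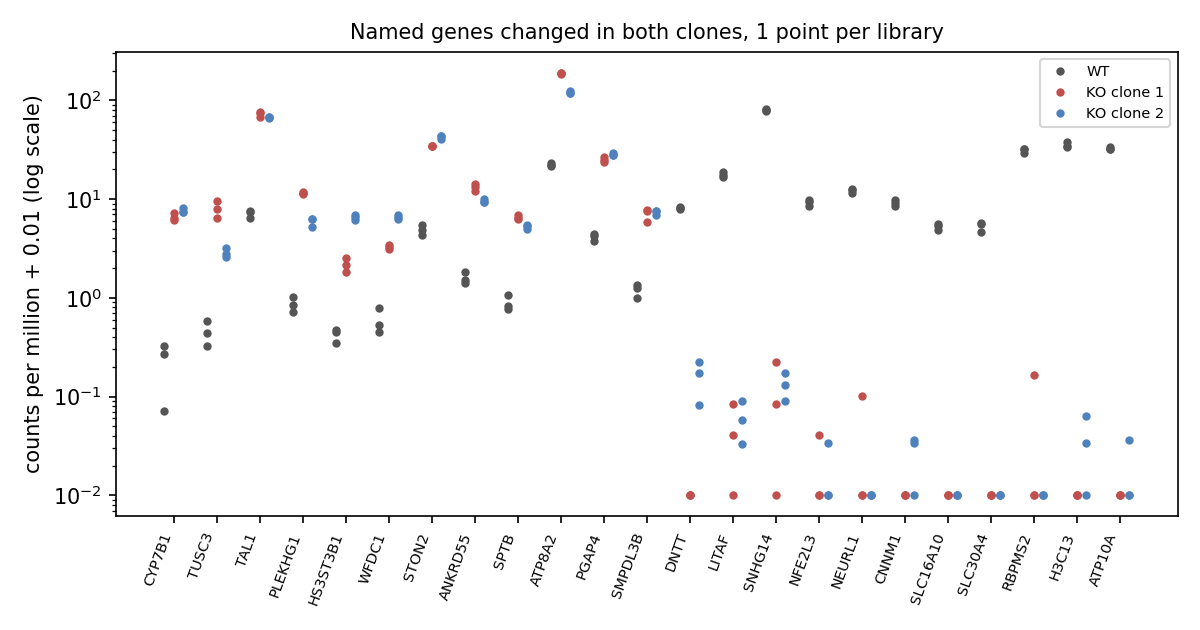
Level in CPM plus 0.01, on a log scale, of 12 named rises and 11 of the 12 named falls (the pseudogene on chromosome Y is left out), 1 point per library, ordered by mean log2 fold change. Points at the lowest level are libraries with 0 counts. For each gene the 6 knockout libraries lie on one side of the 3 WT libraries, which the rule for naming required.

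Of the 43 gene lists, 17 were called in the mean of both clones, 4 higher and 13 lower. With an estimated correlation, 6 of them held: T and NK cell markers, chemokines and cytokines, interferon-stimulated genes, MHC class I presentation and adhesion genes were lower, and stem and progenitor genes were higher. The number of lists called with the preset correlation does not stand out from regroupings. In a fit of 6 against 3 libraries it was 13, and 19 of the 84 ways to split the libraries gave as many, whereas with an estimated correlation no other split called a list. Adjusted over the list alone, the numbers of called members were the same as over all genes for these 6 lists. Of the 56 named list members called in the mean of both clones, 54 had all 6 knockout libraries on one side of the WT libraries. The exceptions were MS4A2 and KRT8. The members were named for a small adjusted p or for calls in both clones, which favours such separation. It is therefore no separate support for the lists.

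T and NK cell markers, which KG-1a cells expressed in part, were lower. Of 24 measured, 10 were called lower and 0 were called higher, with a median log2 fold change of -0.80 (adjusted p = 8.66e-12, and adjusted p = 0.0349 with an estimated correlation). At the adjusted p alone, 19 were lower and 2 were higher. CD3D, a chain of the T cell receptor complex, went from 290 ± 8.50 CPM in WT to 119 ± 4.22 in clone 1 and 149 ± 6.49 in clone 2, a mean log2 fold change of -1.12. CD3E changed by -1.69, from 52.9 ± 1.59 CPM to 14.5 ± 1.14 and 18.4 ± 0.524. The granule protease GZMA changed by -2.87 and the NK granule gene NKG7 by -0.88.

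MHC class I presentation genes and interferon-stimulated genes were lower as lists. All 18 measured MHC class I presentation genes were lower at the adjusted p, and 2 of them passed the fold minimum (median -0.44, adjusted p = 2.8e-17, and adjusted p = 0.0349 with an estimated correlation). HLA-B went from 652 ± 9.42 CPM in WT to 199 ± 8 in clone 1 and 399 ± 22.3 in clone 2, a mean change of -1.21. The peptide transporter TAP1 changed by -1.09, HLA-C by -0.82 and HLA-E by -0.61. With apeglm shrinkage in a 2-group fit, HLA-B was at -0.94 and TAP1 at -0.98, just short of the fold minimum. Of 42 interferon-stimulated genes, 31 were lower and 4 were higher at the adjusted p, and 5 and 1 passed the fold minimum (median -0.43, adjusted p = 6.45e-14, and adjusted p = 0.0036 with an estimated correlation). The guanylate-binding protein GBP1 changed by -1.54, from 95.7 ± 3.62 CPM to 25.4 ± 1.21 and 42.7 ± 2.42. The antiviral gene TRIM22 changed by -1.28 and GBP5 by -0.86. IFITM3, which restricts virus entry, went the other way, from 6.32 ± 0.425 CPM to 24.1 ± 1.40 and 30.1 ± 1.29, a change of 2.10.

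Chemokines and cytokines were lower. Of 23 measured, 9 were called lower and 0 were called higher with edgeR (median -0.63, adjusted p = 2.96e-06, and adjusted p = 0.0454 with an estimated correlation). At the adjusted p alone, 14 were lower and 2 were higher. LTB, the membrane-bound lymphotoxin, went from 56.2 ± 1.57 CPM to 18.0 ± 1.56 and 25.3 ± 1.83, a mean change of -1.40. The differentiation factor LIF changed by -4.12, from 8.12 ± 0.565 CPM to 0.209 ± 0.132 and 0.984 ± 0.144. CCL5, a chemokine of T cells and monocytes, changed by -5.18, from 4.88 ± 0.247 CPM to 0.172 ± 0.124 and 0.0958 ± 0.0970. XCL1 changed by -1.74, IL15 by -1.78 and IL12A by -2.99, and all 3 were called in both clones. IL32, the most abundant of those named, changed by -0.90, from 556 ± 24.7 CPM to 250 ± 6.25 and 358 ± 23.9. NF-kB target genes were not called as a list (adjusted p = 0.12). Of 26 measured, 1 was called, the protease gene PLAU, which rose by 1.15 from 3.45 ± 0.375 CPM to 7.66 ± 0.596 and 7.69 ± 1.17.

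Adhesion and migration genes were lower on balance, with 6 called lower and 1 higher of 34 measured (median -0.18, adjusted p = 0.00011, and adjusted p = 0.0349 with an estimated correlation). The laminin receptor chain ITGA6 went from 121 ± 2.58 CPM to 43.7 ± 0.525 and 63.6 ± 2.37, a change of -1.20, and the junctional protein JAML changed by -4.23. PECAM1 rose by 1.10. Stem and progenitor genes were higher on balance, with 17 higher and 4 lower of 30 at the adjusted p, and 2 and 1 past the fold minimum (median 0.22, adjusted p = 2.36e-06, and adjusted p = 0.0349 with an estimated correlation). Beside TAL1, the transcription factors ERG and LYL1 each rose by 0.47, from 92.5 ± 0.258 CPM to 143 ± 5.97 and 114 ± 3.69 and from 139 ± 7.02 CPM to 203 ± 6.99 and 182 ± 7.12. HLF, a stem cell transcription factor, fell by 3.39, from 2.32 ± 0.409 CPM to 0.244 ± 0.0881 and 0.195 ± 0.126.

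**Figure D4:**
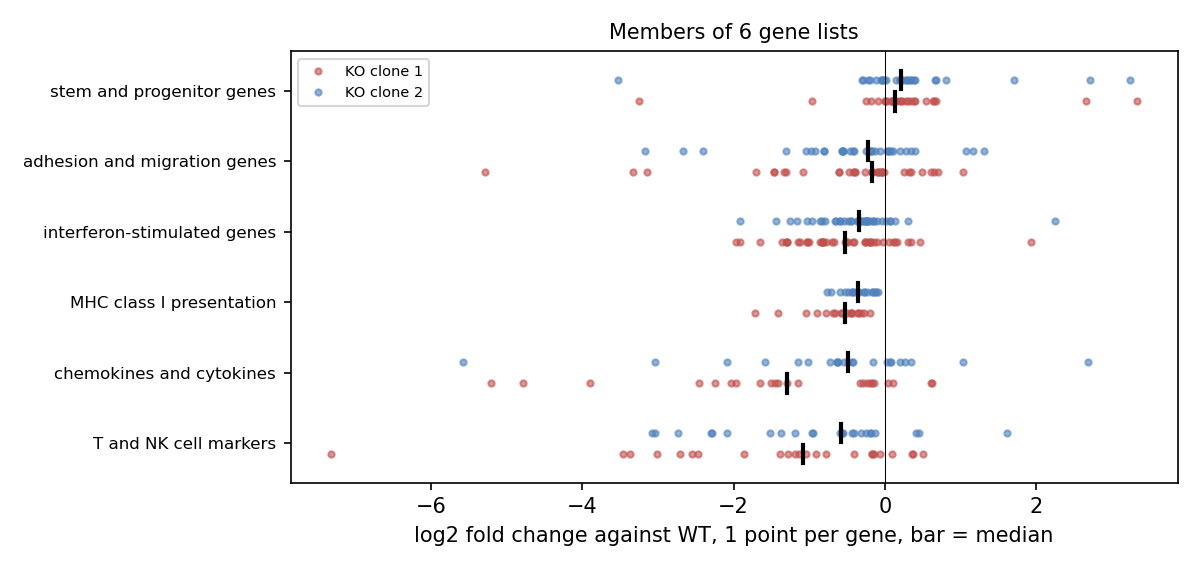
Log2 fold change against WT of each measured member of the 6 gene lists that held with an estimated correlation, 1 point per gene and clone, with black bars at the median. T and NK cell markers, chemokines and cytokines, MHC class I, interferon-stimulated and adhesion genes lie mostly below 0 in both clones, and stem and progenitor genes mostly above 0.

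The other 11 called lists did not hold with an estimated correlation. WNT target genes had a median of -0.38 (adjusted p = 0.161 with an estimated correlation) and 4 of 11 members called lower. The secreted WNT inhibitor NOTUM changed by -4.66 and the receptor FZD7 by -1.33 (-0.93 and not called with apeglm shrinkage in a 2-group fit). LEF1 changed by -0.73, from 324 ± 0.952 CPM to 173 ± 8.50 and 220 ± 2.52. ABC transporters had a median of -0.24 (adjusted p = 0.0967 with an estimated correlation). The cholesterol exporter ABCA1 changed by -1.61, from 39.0 ± 0.201 CPM to 11.1 ± 0.775 and 14.7 ± 0.205. Innate immune sensing genes had a median of -0.10 (adjusted p = 0.0967 with an estimated correlation), and the inflammatory caspase gene CASP1 changed by -0.98. B cell markers had a median of -0.32 (adjusted p = 0.14 with an estimated correlation), with 2 of 8 called lower, DNTT and POU2AF1, and 3 when adjusted over the list alone. Retinoid response genes had a median of -0.26 (adjusted p = 0.136 with an estimated correlation), and STRA6 changed by -0.74.

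The unfolded protein and integrated stress response list had a median of -0.08 (adjusted p = 0.29 with an estimated correlation). In it PHGDH, the first enzyme of serine synthesis, went from 10.5 ± 0.375 CPM to 0.262 ± 0.0397 and 0.0729 ± 0.0382, a change of -6.20, and TRIB3 changed by -1.12. Glycolysis genes had a median of -0.11 (adjusted p = 0.29 with an estimated correlation), with HK1 at -0.49 and GPI at -0.50. Cholesterol biosynthesis genes had a median of -0.10 (adjusted p = 0.265 with an estimated correlation), with DHCR7 at -0.21. Cytosolic ribosomal proteins had a median of 0.11, DNA replication genes one of 0.06 and replication-dependent histones one of 0.06. Their adjusted p with an estimated correlation was 0.412, 0.412 and 0.663. RPS2 rose by 0.23, the DNA polymerase gene POLE by 0.74 and H2AC15 by 0.23. No gene of these last 5 lists passed the fold minimum in edgeR, while at the adjusted p alone 13 glycolysis, 13 cholesterol, 0 ribosomal, 3 replication and 0 histone genes were lower and 2, 0, 20, 15 and 6 were higher. The histone list does not hold H3C13 or its neighbour H2BC18, which was at -5.92 and was chosen after its values were seen.

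A further 11 lists were not called but had at least 3 called members, most of them moving both ways. In the TGF-beta and SMAD list (adjusted p = 0.993), the inhibitory SMAD6 went from 392 ± 11 CPM to 106 ± 2.61 and 127 ± 4.6, a change of -1.75 (SE 0.027, adjusted p = 1.12e-38). The TGF-beta co-receptor ENG changed by -1.67, from 120 ± 3.58 CPM to 49.3 ± 0.761 and 28.8 ± 1.12, and SMAD7 by 0.75. The list had 4 members called lower and 2 higher, a median of 0.03 and a mean of -0.09. Granulocyte markers (adjusted p = 0.0976) had 4 called lower and 1 higher and included CEBPA, the transcription factor of granulocyte differentiation, at -1.34, from 42.2 ± 1.99 CPM to 17.7 ± 0.964 and 15.7 ± 1.62, and the G-CSF receptor CSF3R at -1.03. Erythroid and megakaryocyte markers (adjusted p = 0.822) included the platelet integrin ITGA2B, which rose by 0.63 from 435 ± 16.1 CPM to 647 ± 13 and 697 ± 11.3, and NFE2, which fell by 1.21. Their median was -0.03 and their mean 0.20. Mast cell, eosinophil and basophil markers (adjusted p = 0.822) had 2 called lower, among them the protease CPA3 at -1.19, and 1 higher, MS4A2 at 1.37, with a median of 0.24. Monocyte and macrophage markers (adjusted p = 0.174) had 5 called lower and 1 higher and included VCAN at -1.91 in the mean. VCAN differed between the clones and was not called in a 2-group fit (-1.46), nor with apeglm shrinkage of such a fit (-0.47). MHC class II genes (adjusted p = 0.508) included the class II transactivator CIITA at -4.04 and the protease CTSS, which rose by 1.83. CIITA was at -0.69 and not called when counts disregarded strand.

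Fibroblast, endothelial and epithelial markers (adjusted p = 0.319) had 2 called higher and 1 lower and included ESAM, which rose by 2.14 from 19.9 ± 0.536 CPM to 102 ± 0.666 and 74.6 ± 1.56. Extracellular matrix genes (adjusted p = 0.319) had 7 members called lower and 2 higher, among them the metalloprotease ADAMTS1 at -3.07, which was at -2.29 and not called in a 2-group fit. MAPK feedback genes (adjusted p = 0.686) had 4 called lower, with DUSP6 at -0.47 and SPRED1 at 0.76. Hypoxia response genes (adjusted p = 0.636) had a median of 0. RORA, at -1.86, from 21.1 ± 0.888 CPM to 5.51 ± 0.570 and 6.16 ± 0.0435, was called lower, and LOX at 2.47 and CA9 at 1.52, chosen after their values were seen, were called higher. Immediate early genes (adjusted p = 0.675) had 3 called higher and 1 lower, with NR4A3 at 1.45 and BTG2 at -0.40, a median of -0.10 and a mean of 0.13.

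The remaining 15 lists were not called in the mean of both clones. Their adjusted p ran from 0.053 for mitochondrially encoded mRNAs to 0.998 for NOTCH target genes. The others were the PRMT family, NF-kB targets, the leukaemic stem cell 17-gene list, HOX genes and cofactors, G2 and M phase genes, p53 targets, apoptosis regulators, nuclear respiratory chain genes, heat shock genes, NRF2 targets, MYC and ribosome biogenesis genes, autophagy and lysosome genes, and chromatin regulators of leukaemia. The leukaemic stem cell list had a median of 0.08 and a mean of -0.06.

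In clone 1 against WT, 1565 genes were called, 537 higher and 1028 lower, which asks what this clone alone shows. The interferon-stimulated list (median -0.52, adjusted p = 0.00519 with an estimated correlation) and the MHC class I list (median -0.53, adjusted p = 0.0486) were lower, and these 2 of 25 called lists held with an estimated correlation. Chemokines and cytokines had a median of -1.29 (adjusted p = 0.0523 with an estimated correlation) and T and NK cell markers one of -1.09 (adjusted p = 0.0523). Adhesion genes had a median of -0.17 (adjusted p = 0.0529 with an estimated correlation) and stem and progenitor genes one of 0.14 (adjusted p = 0.0523). G2 and M phase genes had a median of 0.15 (adjusted p = 0.113 with an estimated correlation). SMAD1, the signal transducer of bone morphogenetic proteins, had 0 counts in clone 1, at least 196-fold lower than its 6.38 ± 0.482 CPM in WT. RBPMS, an RNA-binding protein gene, rose in clone 1 by 5.09, from 2.09 ± 0.273 CPM to 71.4 ± 0.831.

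In clone 2 against WT, 1232 genes were called, 379 higher and 853 lower. Of 14 called lists, 5 held with an estimated correlation: interferon-stimulated genes (median -0.34, adjusted p = 0.00419), MHC class I (median -0.35, adjusted p = 0.0489), T and NK cell markers (median -0.58, adjusted p = 0.0489), adhesion genes (median -0.22, adjusted p = 0.0489) and stem and progenitor genes (median 0.21, adjusted p = 0.0489). Chemokines and cytokines did not hold (median -0.49, adjusted p = 0.0875). G2 and M phase genes had a median of -0.09 (adjusted p = 0.237 with an estimated correlation). The X-linked gene ARMCX5 had 1 count in clone 2, a ratio of WT to clone 2 of 1680 (95% counting interval 300 to 66300), and PRRG1, a vitamin K-dependent membrane protein gene, had 1 count, a ratio of 1190 (213 to 47000).

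**Figure D5:**
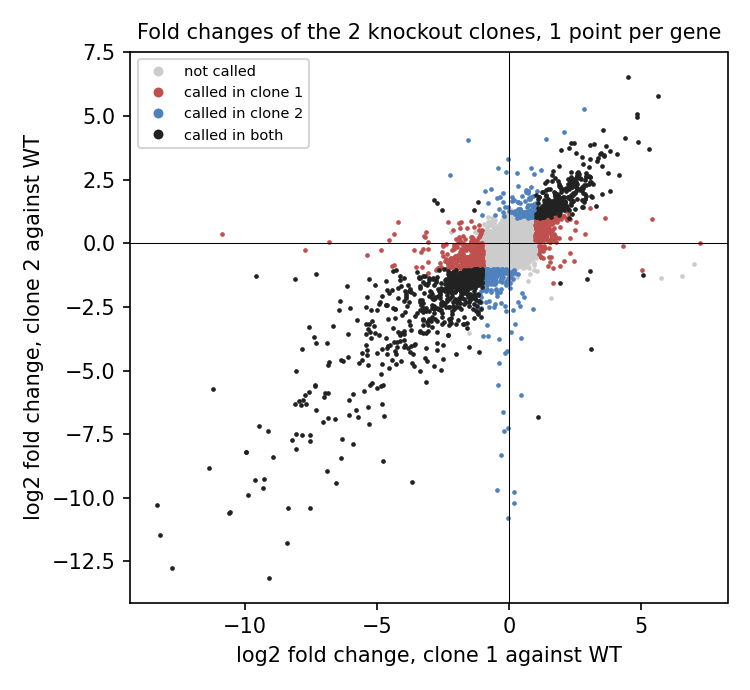
Log2 fold change against WT in clone 1 (x axis) and clone 2 (y axis) for each of 20655 genes, coloured by whether the gene was called in clone 1, clone 2, both (in the same or in opposite directions) or neither. Most genes called in both lie near the diagonal, 628 of them lower and 269 higher, and 11 were called in opposite directions.

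The overlap of the clones was far above that of unrelated lists. Independent lists of the same sizes would share 9.9 higher and 42.5 lower genes, against 269 and 628. The shared genes were 50.1% of the rises and 61.1% of the falls of clone 1, and 71.0% and 73.6% of those of clone 2. Both comparisons use the same 3 libraries of 1 WT group, which alone makes their fold changes correlate. Across genes, Pearson's r between the clones was 0.782, against a mean of 0.49 and a highest of 0.513 in 20 simulations with no change in either clone. The covariance was 0.504, against a mean of 0.0258 in the simulations, a difference of 0.478. The simulations shared at most 2 called genes. Since the WT libraries are too few to divide between the clones, a part of the excess in shared called genes from the shared controls cannot be excluded.

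The clones also differed from each other, which the comparison of clone 2 with clone 1 measured. In clone 2 against clone 1, 582 genes were called, 327 higher and 255 lower in clone 2. SMAD1 was at 8.25 ± 0.810 CPM in clone 2 and had 0 counts in clone 1. The cytoskeletal gene NAV2 had 1 count in clone 1 and 4.41 ± 0.535 CPM in clone 2. The circadian transcription factor ARNTL was at 0.210 ± 0.104 and 6.30 ± 0.240 CPM, EPB41L5 at 0.766 ± 0.101 and 19.9 ± 0.435 CPM, PHACTR3 at 0.423 ± 0.158 and 14.1 ± 1.04 CPM, and RNF150 at 0.0739 ± 0.0323 and 1.76 ± 0.0968 CPM in clones 1 and 2. The calcium channel subunit gene CACNA2D1 was called lower in clone 1 (-2.53) and higher in clone 2 (1.31), from 6.64 ± 0.0433 CPM in WT. DNTT was also among the 8 largest differences in this direction.

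In the other direction, ARMCX5 was at 15.7 ± 0.258 CPM in clone 1, and the neighbouring GPRASP1 at 5.46 ± 0.479 CPM in clone 1 and 0.0312 ± 0.0540 in clone 2. ARMCX5-GPRASP2, a readthrough transcript that overlaps ARMCX5, had 0 counts in clone 2, at least 247-fold lower than in WT. Read pairs that the overlapping genes share cannot be assigned to 1 of them. PRRG1 was at 7.10 ± 0.790 CPM in clone 1. RBPMS was at 0.869 ± 0.123 CPM in clone 2, and the oestrogen-responsive gene GREB1 was at 10.6 ± 0.968 CPM in clone 1 and 0.514 ± 0.0865 in clone 2. Both were called in opposite directions against WT. CGREF1 was at 1.44 ± 0.311 and 0.0237 ± 0.0234 CPM, and the transcription factor KLF11 at 5.14 ± 0.415 and 0.256 ± 0.0190 CPM.

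Of 657 genes called in clone 1 only, 204 differed between the clones by the same thresholds, and of 324 called in clone 2 only, 108 did. Among the lists, 19 were called, 16 higher and 3 lower in clone 2, and 6 of them held with an estimated correlation. G2 and M phase genes were lower in clone 2 (median -0.22, adjusted p = 0.0368 with an estimated correlation), with 28 of 31 lower at the adjusted p. MYC and ribosome biogenesis genes were higher (median 0.24, adjusted p = 0.0368), with 26 of 31 higher. MHC class I (median 0.24, adjusted p = 0.0485), interferon-stimulated genes (median 0.14, adjusted p = 0.0368), cholesterol biosynthesis genes (median 0.16, adjusted p = 0.0485) and the leukaemic stem cell list (median 0.16, adjusted p = 0.0485) were also higher in clone 2. HLA-B differed by 1.01, so its decrease was smaller in clone 2.

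In the authors' deposited table, 1467 genes had an adjusted p under 0.05 and an absolute log2 fold change of at least 1, 454 higher and 1013 lower in the knockout. Of these, 1011 were among the genes tested here, 965 were called here in the same direction in the mean of both clones, and 768 were called in both clones. Spearman's rho between the log2 fold changes of the authors' deposited table and those of the mean contrast was 0.92 across 20482 genes, which are not independent replicates. PRMT2 was at -0.90 in the authors' deposited table.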

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

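The comparison of the clones was planned before the data were examined. Of the tests on the library rich in mitochondrial rRNA, the one on nuclear rRNA was planned before its value was seen and the one on mitochondrial mRNA was chosen afterwards.

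The change against WT differed between the clones for 582 genes, by a test of clone 2 against clone 1. With 1 WT group, a differing effect of the knockout and other differences between clones cannot be told apart. Any other split of the 6 knockout libraries into 3 and 3 called at most 0 genes, and the real split was 1 of 10 splits, which are too few for a share under 0.05. Differences are given as the log2 fold change of clone 2 minus that of clone 1. Clone 2 was higher for SMAD1 by 11.22, NAV2 by 8.27, DNTT by 5.46, PHACTR3 by 5.05, ARNTL by 4.91, EPB41L5 by 4.71, RNF150 by 4.47 and CACNA2D1 by 3.85. It was lower for ARMCX5-GPRASP2 (-10.75), ARMCX5 (-10.40), PRRG1 (-9.24), GPRASP1 (-7.23), RBPMS (-6.35), CGREF1 (-5.69), GREB1 (-4.36) and KLF11 (-4.31). Some of these sizes depended on the processing. Over the alternatives ARNTL ran from 1.285 to 5.187, EPB41L5 from 2.778 to 4.806, RBPMS from -6.458 to -2.287 and CGREF1 from -6.486 to -1.142. For SMAD1, NAV2, DNTT, ARMCX5-GPRASP2, ARMCX5, PRRG1 and CGREF1, 1 clone had 0 to 3 counts, so the fitted size depends on the prior count and is no bound.

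Among genes called in both clones, the size of the change differed for TUSC3 (-1.48), HS3ST3B1 (1.61), WFDC1 (1.01) and RBPMS2 (-4.06, with 5 and 0 counts in the clones). PHGDH was lower in clone 2 by -1.77. The fall was smaller in clone 2 for LIF by 2.17, XCL1 by 1.45, JAML by 2.11, POU2AF1 by 1.40, KRT7 by 2.19, ADAMTS1 by 3.15 and HIC1 by 1.96. It was also smaller for HLA-B by 1.01, VCAN by 2.33, ITGB3 by 1.91, THBS1 by 1.46, DUSP4 by 1.20 and FZD7 by 1.26, which were called in clone 1 but missed the fold minimum in clone 2. MS4A2, called in clone 2 but not in clone 1, was higher in clone 2 by 1.34.

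For 19 gene lists the clones differed with the preset correlation, and the highest number among the other 9 splits was 11. The real split was 1 of 10, again too few for a share under 0.05. Median differences of the 6 that held with an estimated correlation were 0.14 for interferon-stimulated genes, 0.24 for MHC class I, 0.16 for the leukaemic stem cell list, -0.22 for G2 and M phase genes, 0.16 for cholesterol biosynthesis and 0.24 for MYC and ribosome biogenesis. The 13 that did not hold had medians of 0.19 for the PRMT family, 0.08 for NF-kB targets, 0.51 for chemokines and cytokines, -0.12 for HOX genes, 0.27 for erythroid markers, 0.29 for T and NK cell markers and 0.63 for B cell markers. The others were 0.18 for glycolysis, 0.15 for the unfolded protein response, 0.21 for heat shock genes (mean -0.02), 0.07 for ribosomal proteins, 0.23 for MAPK feedback genes and -0.16 for histones.

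KO clone 1 replicate 1 had 13.33% multimapping pairs, far above the 3.86% to 4.34% of the WT libraries, in totals that the comparisons do not use. More mitochondrial RNA of every kind is argued against: the share of mitochondrial mRNAs rose by 0.229 on the log2 scale, 2.64% of the 8.684 by which the mitochondrial rRNAs rose. Incomplete removal of rRNA before sequencing may account for the pattern and stays open. The test fixed for it asked for nuclear rRNA genes and pseudogenes at 3 times the highest other library or more, and the value was 0.236 times (38.3 against 162 CPM), which met the bound set against this explanation. That bound is set aside here, after the value was seen, because uniquely mapped counts leave out reads from the repeated rRNA copies and because the library with the highest value, WT replicate 3, had 4.34% multimapping pairs; in the other 7 libraries the level was 23.3 to 26.2 CPM.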

How the results depend on the processing

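The alternatives were planned before the data were examined, except the DESeq2 fits in the layout of the authors' deposited table and the thresholds for genes off in both clones. Results are given in the order clone 1, clone 2, mean of both clones, clone 2 against clone 1, and both clones in the same direction. With at least 1 CPM in 3 libraries the numbers of called genes were 967, 768, 830, 347 and 591, since fewer genes were tested. With no fold minimum they were 7475, 6293, 7282, 5355 and 4040, since the rule then takes smaller changes. An estimated correlation left 2, 5, 6 and 6 called lists, and fry called 33 lists in clone 2 and 33 in the mean; fry asks whether a list moves at all and not whether it moves more than other genes. In the layout of the authors' deposited table, DESeq2 called 1475 genes, and 2079 with an unadjusted p under 0.05. Other thresholds for the genes off in both clones gave 15 with a WT minimum of 10 CPM, 14 with a clone maximum of 0.1 CPM and 14 with counts without regard to strand, against 25.

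All other alternatives kept these numbers within 1.5 times, including all 90 values with 1 library left out. PRMT2 stayed between -0.92 and -0.90. With the replicate block, the numbers were 1557, 1228, 1349, 577 and 895 genes and 25, 17, 18 and 20 lists. Replicate numbers do not pair the samples: residuals of libraries with the same number had r from -0.014 to 0.012 across genes, against -0.027 to 0.024 with other numbers. A fit to only the groups compared was not applicable to the mean of both clones. Relative log expression scaled the libraries almost as the trimmed mean of M-values did, so its refits say nothing about scaling.

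The 177 values of named genes were refitted 3003 times. The side of the threshold was kept in 2939 refits, lost in 63 and gained in 1, and 0 values called in either fit reversed. Values called in neither fit could change sign and still count as kept. In the mean of both clones, CACNA2D1 ran from -0.678 to 0.438 and PRMT3 from -0.051 to 0.02 over the refits. Of those lost, 25 came with apeglm and 20 with a 2-group fit, where the spread between the clones counts as spread within the knockout group, and 9 with counts without regard to strand (SPTB 0.24, NFE2L3 -0.66, CIITA -0.69, CD74 -0.09, ETV4 -0.87, HIC1 -0.89, THBS1 -0.55, RBPMS 0.92 and JUN -0.995). The cause of the latter was not tested. Both apeglm and the 2-group fit ended the calls of SMAD1, NAV2, PHACTR3, ARNTL, EPB41L5, RNF150, ARMCX5-GPRASP2, ARMCX5, PRRG1, GPRASP1, RBPMS, KLF11, OSM, VCAN, ITGB3, KRT8, THBS1, DUSP4 and ID2 in the mean of both clones. The edgeR 2-group fit alone ended that of ADAMTS1 (-2.29), and apeglm alone those of RBPMS2 (-0.18), CGREF1 (-0.21), HLA-B (-0.94), TAP1 (-0.98), JUN (-0.96) and FZD7 (-0.93). For the mean of both clones apeglm was itself applied to a 2-group fit in DESeq2. The 2 alternatives are therefore not separate checks, and losses with apeglm cannot be assigned to shrinkage alone. With 1 library left out, JUN was at -0.97 without KO clone 1 replicate 1, -0.91 without KO clone 2 replicate 1 and -0.88 without WT replicate 1. KRT8 missed the adjusted p without WT replicate 1 (1.22), WT replicate 3 (1.32), KO clone 2 replicate 1 (1.35) and KO clone 2 replicate 2 (1.36). OSM was at -0.98 without WT replicate 1, and without WT replicate 3 ID2 was at -0.99 and COL3A1 at 1.01. Depth limits genes near 0 counts, where a change below the floor of 0.07 to 0.107 CPM per library cannot be seen.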

Other observations

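The tests on genes off in both clones were chosen after the pattern was seen, apart from the count of splits, and the tests on strand were planned before their values were seen.

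A group of 25 genes was on in WT, at 5 CPM or more, and off in both clones, below 0.3 CPM, and 23 of them were protein coding. Beside the named falls and PHGDH they were, chosen after their values were seen, APBB1IP, an adaptor of integrin activation (23.6 ± 1.10 CPM in WT), the actin nucleator SPIRE1 (22.9 ± 0.879 CPM), profilin PFN2 (17.7 ± 0.699 CPM), CIDEB (15.9 ± 0.774 CPM), MCC (14.9 ± 0.603 CPM), NEURL1B, DHX32, NIPA1, KLF3, HAPLN3, DOCK9 and the B cell receptor phospholipase PLCG2. Their 6 genes on chromosome 15 were SNHG14, ATP10A, NIPA1, RBPMS2, SLC30A4 and HAPLN3, against 0.841 expected from the 11188 genes on in WT (Fisher's exact test, p = 0.000144, adjusted p = 0.00346 over 24 chromosomes), and 5 were on chromosome 10 against 0.958 (adjusted p = 0.0272). Fisher's test takes the genes as independent, which neighbours may not be, and SNHG14 and ATP10A lie within 400 kb of each other. The opposite pattern, off in WT and on in both clones, was seen for 1 gene, CYP7B1.

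In the Prader-Willi and Angelman region, chosen after its values were seen, SNRPN went from 3.29 CPM to 0 counts in both clones together with SNHG14, while UBE3A, which overlaps SNHG14, was at 273, 285 and 305 CPM in WT, clone 1 and clone 2. Near NIPA1, CYFIP1 went from 12.3 CPM to 63.5 and 27.4, and NIPA2 was at 72.4, 67.3 and 75.7 CPM. Of the 11 genes called in opposite directions, 6 rose in clone 1 and 5 in clone 2. Among them, chosen after their values were seen, the heat shock gene HSPB1 went from 4.6 CPM to 17.4 in clone 1 and 1.55 in clone 2, and the growth factor receptor PDGFRA from 1.00 CPM to 0.443 and 3.15.

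For the 25 genes off in both clones, random silencing in each clone on its own is argued against as the whole cause. There were 40 genes off in clone 1 and 32 in clone 2, so independent lists would share 0.114. That number takes each gene on in WT as equally likely to be silenced. More genes would be shared if some were more prone to silencing, and that case was not tested. Loss of chromosome regions that reach most neighbouring genes is argued against too: the median over genes of the median log2 fold change of all other tested genes within 400 kb was -0.041, the lowest median -0.187, and 16 of 283 pairs of gene and neighbour were at -1 or lower. Smaller losses stay open, among them one of SNRPN with the adjoining start of SNHG14. UBE3A, which overlaps the far end of SNHG14 and lies before ATP10A, was at 0.109. That value argues against a loss of all of SNHG14, and against one in a single piece from SNRPN to ATP10A. Cells of a listed other type in the WT culture stay open. At most 25% of a list's members on in WT were off in both clones (DNTT, 1 of 4 B cell markers). However, the level of the others in the clones themselves would hide a small share. T and NK cell markers were at a median of -0.80, with CD3D at -1.12. The monocyte and macrophage marker LST1 was at -0.21 and the granulocyte marker CSF3R at -1.03. A state of the WT culture, or of a parent cell from which both clones came, may have set these genes apart instead of PRMT2 loss, and these cannot be told apart because the design has 1 WT group.

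The shared changes were set against other splits of the 9 libraries. For genes called in both clones, 1 of 100 splits into 3 groups gave as many as the real one, with 897 against at most 192 in the others, so chance can be excluded for libraries regrouped one by one. For 6 against 3 libraries, the real split called 1144 genes and the highest other 396, 1 of 84, so chance can be excluded in the same sense. The highest others set the libraries of clone 1 apart (396 and 192 genes), a structure of the samples, and 81 of the 84 splits called 0 genes with edgeR. Only 3 of the 84 keep each group of 3 libraries whole, with 1144, 396 and 146 genes, so differences by chance between whole cultures or clones are not excluded. For lists with the preset correlation chance cannot be excluded: 19 of 84 splits gave as many as the real 13, with up to 18. With an estimated correlation the real split gave 5 lists and the others 0, 1 of 84 splits, which excludes chance only for libraries regrouped one by one. The split with clone 1 apart called 396 genes and yet 0 lists. The 0 lists thus say little about chance differences between whole cultures or clones. For clone 1 against WT the real values were 1565 genes and 25 lists and the highest others 0 and 11, and for clone 2 against WT 1232 genes and 14 lists against 0 and 11. Those comparisons have 10 splits, too few for a share under 0.05.

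Counting without regard to strand called 1501 genes in the mean of both clones, and 392 of them were not called on their own strand. The 344 genes with under 50% of their reads on their own strand were examined on the opposite strand alone. It changed by a median of 1.435 on the log2 scale in the direction of the call. The choice of these genes fixes that outcome, so the median decides nothing. Where the own-strand share was near 0, as for RBMY2OP and RGS7BP (0%) and DGKB (0.05%), nearly all counted reads were of the opposite strand. For such genes the call rests on reads of the opposite strand by construction. Where both strands held many reads, opposite-strand reads stay open as an explanation. Of the 21 genes with at least 90% on their own strand, 17 were tested, and their fold change moved by a median of 0.153. This lay between the bounds set for and against, so the explanation stays open there too. For a further 27 genes the share was between 50% and 90%, and no bound was set.

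The authors' deposited table labels 2078 genes as changed, 664 higher and 1414 lower. In all 60605 genes these labels equal an unadjusted p under 0.05 with an absolute log2 fold change of at least 1; 486 labelled genes have an adjusted p of 0.05 or more and 125 have none. Its fold changes divided by their SE equal its test statistic within 1.7e-13, as for estimates without shrinkage, and it lists all 60605 genes. The series text states apeglm shrinkage, removal of genes with low counts and an adjusted p under 0.05, so the table differs from the stated methods in these steps. A DESeq2 fit of 6 against 3 libraries with counts without regard to strand and no filter, chosen after the data had been seen, gave a log2 fold change within 0.01 of the authors' deposited table in 45106 of 45107 genes.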
